A study of Mus musculus with 7 samples.

How the data were processed

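Gene expression was measured with 7 Illumina mouse bead arrays, 1 per RNA sample, of cells from OG2 mice. OG2 mice carry a green fluorescent protein reporter driven by regulatory sequence of Pou5f1. The groups, taken from the sample labels, were lineage-negative bone marrow cells (LinNeg_BM, 1 array), embryonic stem cells (ESC, 1 array), induced pluripotent stem cells (iPSCs) made from lineage-negative bone marrow cells (LinNeg_iPSC, 3 arrays of the separate lines 1.1.2, 7 and 9), iPSCs made from lineage-positive bone marrow cells (LinPos_iPSC, 1 array of line 1.1) and iPSCs made from embryonic fibroblasts (MEF_iPSC, 1 array). Per the labels' protocols, total RNA was amplified and biotin-labelled with an in vitro transcription step of 12 h. The tissue field of the labels reads bone marrow for all 7 samples, also for ESC and MEF_iPSC, so the groups rest on the cell type field. The labels count each line as 1 biological replicate and do not say whether the lines came from separate animals, so the spread between lines may include no variation between animals.

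The deposited table held, for 25697 probes and each array, a bead-summarised intensity on a linear scale, which the values show to be neither background-subtracted nor scaled between arrays. The same deposited table held a detection p-value per probe and array, apparently the share of negative-control beads at least as bright. A second table held the authors' processed values on a log2 scale, with the same distribution on all 7 arrays (median 3.913 on each) and in the same order as the intensities within each array (Spearman correlation across probes 1). BeadStudio 3.2, RMA and lumi are named in the submitters' processing notes, with no role, order or setting, so the authors' background method is not given in the sources used here. That second table was used only as an alternative.

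Intensities were background-corrected with the negative-control distribution inferred from the detection p-values (limma's neqc, offset 16), quantile-normalized and taken to log2. A probe was called above background on an array at a detection p-value under 0.01. Genes were named through the platform's probe annotation, in which 23978 probes had 1 gene symbol, 0 had several and 1719 were not listed. Of the named probes, 23962 matched a gene table of assembly GRCm38.p6 by gene identifier. That table served for chromosomes and for the order of genes, and no coordinates are given because the probes' own genome build was not used here. Probes above background on at least 1 array numbered 13427, and the probe with the highest mean over all arrays stood for its gene, which left 9263 genes to test, 2445 of them with more than 1 probe above background. No column of values was left unused. Array medians lay between 103 and 134.9 intensity units, and 40.56% to 42.43% of probes were above background.

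Differences were tested with limma (lmFit and eBayes) in 1 fit with 5 groups, with p-values adjusted by the Benjamini-Hochberg method within each comparison and a threshold of 0.05. The residual spread came from the 3 LinNeg_iPSC lines alone (2 residual degrees of freedom, 3.157 prior degrees of freedom), so each lone array was assumed to vary like these lines. The 4 comparisons were LinNeg_iPSC against LinNeg_BM, ESC, MEF_iPSC and LinPos_iPSC. The lone arrays were not tested against one another. A gene below background on all arrays of a group has only a bound there. Its difference is given as at least N-fold, from the mean log2 value of the brighter group against the higher of the dim probe's own value and the lowest value above background on each dim array. Where 1 or 2 of the 3 lines were below background, only those lines' values were raised in the same way for the bound.

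Fixed before the data were examined were the grouping, the tests, the alternative settings, the gene lists and the rule for named genes. The rule took, per comparison, the 10 largest rises and 10 largest falls among genes past the test whose 3 lines all lay on one side of the other array, or the 5 widest gaps where fewer than 3 genes passed in a direction. It also took up to 4 members of each list with the largest absolute difference, and a fixed set (Pou5f1, Nanog, Sox2, Klf4, Myc, Ptprc, Spi1, Dlk1 and sex-linked genes among them). Lists numbered 22: naive pluripotency, primed and early lineage, extraembryonic endoderm, hematopoietic stem and progenitor, pan-leukocyte, granulocyte-monocyte, erythroid-megakaryocyte-mast, lymphoid, fibroblast or feeder, epithelial junction, germline and early-embryo, Dlk1-Dio3 imprinted, other imprinted, DNA methylation and polycomb, cell cycle, cell-cycle inhibitor and p53, stress response, interferon and MHC class I, Hox clusters, reprogramming factors, sex-linked and housekeeping. The 19 lists with at least 5 measured members were tested with limma's camera, with a preset correlation of 0.01 and, as an alternative, an estimated correlation, and adjusted over the 19 lists within a comparison.

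Retention of bone marrow genes was the median LinNeg_iPSC minus MEF_iPSC log2 difference over genes above background in LinNeg_BM and at least 4 times brighter there than in ESC, set against 10000 random lists of the same size matched on mean expression. Similarity was the Pearson correlation across genes between arrays. Alternatives were normexp background correction (offset 50), no background correction, scaling of arrays to a common median, cyclic loess, the authors' values, no filter, a filter requiring 3 arrays above background, all probes, the mean of a gene's probes, eBayes with trend and robust, a 2-fold minimum, pooling of the other pluripotent arrays, and leaving out each line. Fits without genes of chromosomes X and Y, and without those of chromosomes 8 and 14, were added after the data were seen.

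The scripts were tested on simulated arrays of the same 9263 genes. Of 50 genes changed by a log2 difference of 1, 2, 3 or 4, the limma fit recovered 12%, 84%, 94% and 98% for LinPos_iPSC, 4%, 84%, 90% and 96% for MEF_iPSC, and 12%, 78%, 94% and 94% for ESC. In a simulation of the bone marrow comparison 94.9% of genes changed at least 2-fold were recovered and 1.306% of calls were false. There 2000 genes were set to no change and the others kept their observed differences. The false share depends on that choice and does not estimate the share in the measured comparison. In all of these simulations the lone array was given the spread estimated from the lines, so other variation of that array was not covered. A simulated list of 15 genes shifted by a log2 of 0.6 had adjusted p = 4.73e-08 in limma's camera with the preset correlation and adjusted p = 0.983 with an estimated correlation. In the measured lists called against ESC the estimated correlation was 0.658 (extraembryonic endoderm), 0.323 (epithelial junction) and 0.129 (fibroblast or feeder), above the preset 0.01. The simulated result therefore does not show that the preset correlation suits these lists. Their calls lost with an estimated correlation need not reflect low power alone. Calculations used R 4.3.3 with limma 3.58.1, and figures used Python 3.11.15 with matplotlib 3.10.9.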

Results

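The 7 arrays profiled 1 bone marrow population and 6 pluripotent cultures. Lineage-negative bone marrow is the fraction left after cells carrying surface markers of mature blood lineages are removed, and it served as the cell of origin of the 3 LinNeg_iPSC lines. The series concerned iPSCs from primitive bone marrow cells and their return to blood lineages, and the arrays address how the lines compared with the cells they came from, with ESC and with iPSCs of other origins. Between 10423 and 10904 of the 25697 probes were above background on each array. The median SD of a gene between the 3 LinNeg_iPSC lines was 0.17 on the log2 scale. Values are normalized log2 intensities, given as mean ± SD over the lines (n = 3), against 1 array without replicates in each other group.

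The first comparison asked how far the LinNeg_iPSC lines had moved from the bone marrow cells they were made from. Of 26 naive pluripotency genes 6 were above background in LinNeg_BM and 25 or 26 in each line. Of 21 granulocyte-monocyte genes, all above background in LinNeg_BM, 1 was so in each line. Of 18 pan-leukocyte genes 6 to 8 were above background in the lines, beside 6 in ESC and 7 in MEF_iPSC, which have no bone marrow origin. Pou5f1, a transcription factor central to pluripotency, was not above background in LinNeg_BM and reached 12.89 ± 0.06 (n = 3) in the lines, at least 150-fold higher (limma, adjusted p = 2.56e-05). Mpo, the myeloperoxidase of neutrophil granules, stood at 14.64 in LinNeg_BM and was below background in all 3 lines at 4.46 ± 0.05 (n = 3), at least 549-fold lower (limma, adjusted p = 2.4e-05).

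Of the 26 measured naive pluripotency genes (30 were on the list), 25 rose and 0 fell, with a median difference of 5.50, or 4.42 with values below background at their bound. A measured gene was above background on at least 1 array, so one dim in LinNeg_BM could hardly do other than rise. That limit applies to every list set against LinNeg_BM. Dppa5a rose at least 481-fold, Esrrb at least 205-fold, Dppa4 at least 127-fold, Nanog at least 119-fold and Sox2 at least 18.8-fold. Klf4, above background in both groups, rose 5.24-fold, and Myc fell at least 2.95-fold to below background. Other large rises were Dnmt3l, a cofactor of de novo DNA methylation (at least 176-fold), the imprinted gene Snrpn (at least 148-fold), Fabp3 (at least 120-fold), Trh (at least 100-fold) and Igfbp2 (at least 86.9-fold). The naive pluripotency list passed limma's camera (adjusted p = 3.38e-13), a call lost at adjusted p = 0.114 with an estimated correlation.

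**Figure D1:**
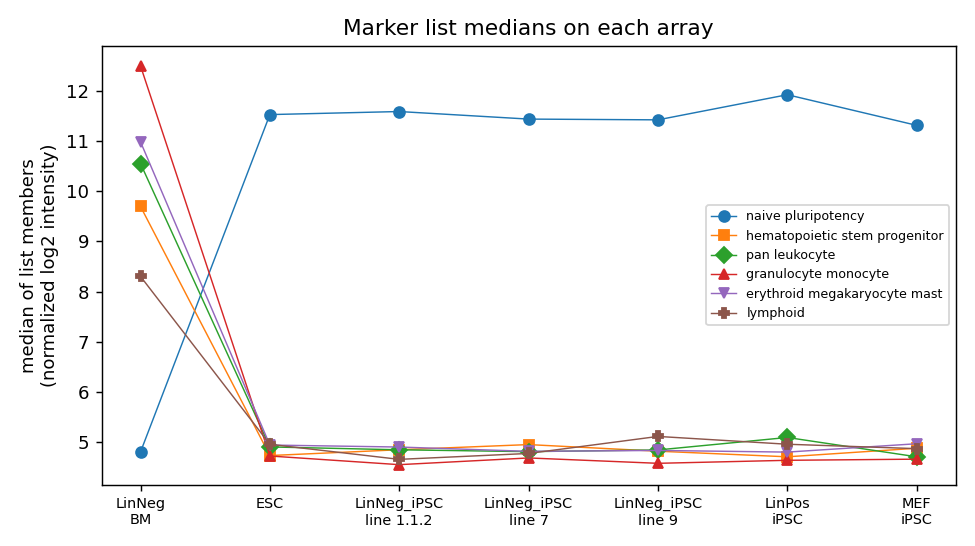
Median normalized log2 intensity (vertical axis) of the members of 6 marker lists on each of the 7 arrays (horizontal axis), each point 1 array and lines joining points of 1 list only to guide the eye. The naive pluripotency median was low in LinNeg_BM and high on all 6 pluripotent arrays, and the 5 blood cell lists ran the other way.

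All 21 measured granulocyte-monocyte genes fell, with a median of -7.69 (-6.81 at the bound). They included the granule proteases Prtn3 (at least 439-fold), Elane (at least 343-fold) and Ctsg (at least 282-fold) and the calcium-binding S100a8 (at least 423-fold). All 20 genes of the erythroid-megakaryocyte-mast list fell, with a median of -5.57 (-5.04 at the bound), among them the alpha globin Hba-a1 (at least 348-fold), Pf4 of platelets (at least 63.0-fold) and Ermap (at least 58.5-fold). All 18 pan-leukocyte genes fell, with a median of -5.18 (-4.32 at the bound). Cd52 fell at least 141-fold and Rac2, a GTPase of blood cells, at least 38.9-fold, while Ptprc, which encodes CD45, fell from 6.05 to 4.69 ± 0.21 (n = 3), at least 1.42-fold. Another Ptprc probe, brighter in LinNeg_BM, stood at 6.985 there and at a mean of 4.387 in the lines, so the size of the fall depends on the probe. Of 15 lymphoid genes 14 fell, with a median of -3.49 (-2.76 at the bound), including Cd74 by 43.3-fold and Vpreb3, a component linked to the surrogate B cell receptor, at least 20.9-fold. Of 15 hematopoietic stem and progenitor genes 14 fell, with a median of -3.39 at the bound and without it. The blood transcription factors Lmo2 and Gfi1b fell at least 177.5-fold and at least 40.03-fold, and Gata2, above background in 1 of 3 lines, at least 53.8-fold. Other large falls were Retnlg (at least 326-fold), Prg2 (at least 289.9-fold) and Lyz1, a lysozyme above background in 1 of 3 lines (at least 398.6-fold). In limma's camera these 5 lists had adjusted p-values between 3.38e-13 and 1.74e-07, and between adjusted p = 0.114 and adjusted p = 0.157 with an estimated correlation. The lists as fixed held 24 genes each, or 22 for pan-leukocyte. Every measured member was above background in LinNeg_BM, and most were dim on the pluripotent arrays. Members that entered only through LinNeg_BM could hardly do other than fall, so the filter partly sets these counts and p-values.

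**Figure D2:**
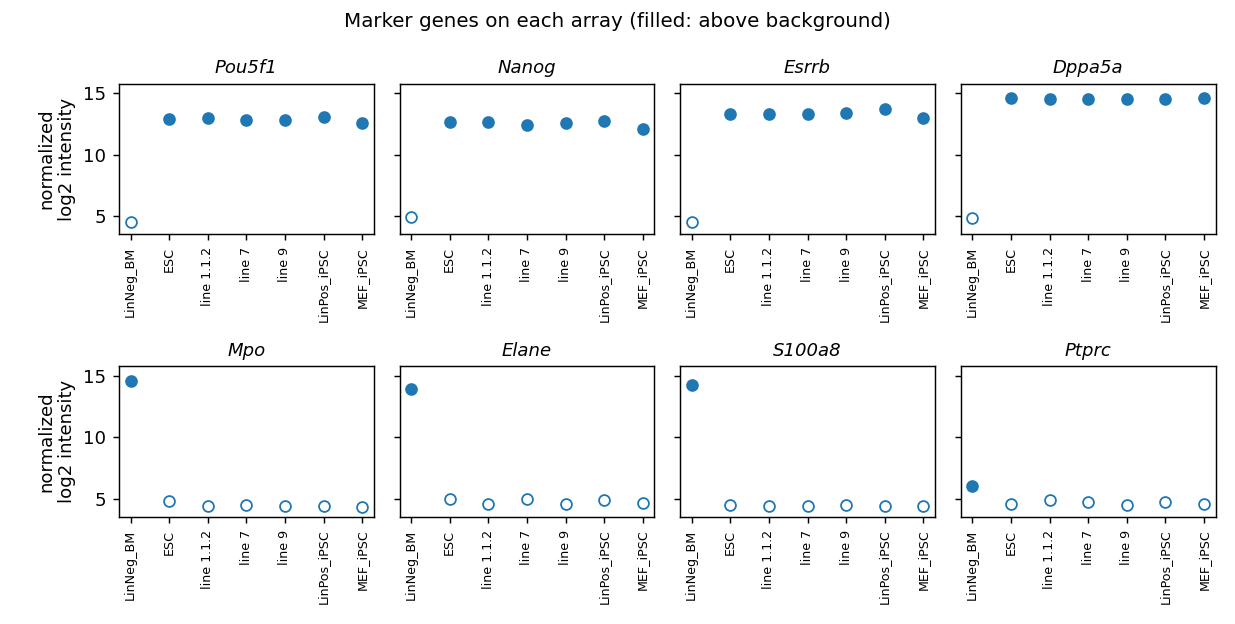
Normalized log2 intensity (vertical axis) of 8 genes on each of the 7 arrays (horizontal axis), with 1 point per array, filled where the probe was above background and open where it was not. Pou5f1, Nanog, Esrrb and Dppa5a were above background on the 6 pluripotent arrays only, and Mpo, Elane, S100a8 and Ptprc on the LinNeg_BM array only.

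A further 5 lists stood higher in the lines by limma's camera, with adjusted p-values between 3.94e-05 and 0.00217, and between adjusted p = 0.157 and adjusted p = 0.424 with an estimated correlation. Of 14 epithelial junction genes 11 rose and 0 fell, with a median of 3.11 (2.61 at the bound), led by the claudin Cldn4 (at least 77.6-fold) and the desmosomal Pkp2 (at least 18.8-fold). Of 14 extraembryonic endoderm genes 11 rose, among them the basement membrane genes Sparc (at least 43.7-fold) and Col4a1 (at least 21.1-fold), with a median of 3.26 (2.05 at the bound). The 1 member that fell was Srgn, a proteoglycan of blood cell granules above background in 2 of 3 lines, from 11.02 to 6.07 ± 1.20 (n = 3). Of 17 fibroblast or feeder genes 11 rose and 2 fell, with a median of 2.04 (1.67 at the bound) and Ccn2 at least 81.1-fold higher. Germline and early-embryo genes rose in 10 of 12 cases, with a median of 2.81 (1.63 at the bound), including Tex19.1 (at least 55.9-fold) and Rhox5 (at least 29.6-fold). The p53 and cell-cycle inhibitor list had 10 genes higher and 2 lower of 12, with a median of 3.34 (2.86 at the bound), and both Ccng1 (20.4-fold) and Cdkn1a, the p21 inhibitor (15.9-fold), rose. Their other probes also stood higher in the lines, by 4.235 and 1.434 on the log2 scale for Ccng1 and 4.023 and 2.92 for Cdkn1a. The size of the rise thus depends on the probe.

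In limma's camera 5 more lists passed, all lost at between adjusted p = 0.214 and adjusted p = 0.265 with an estimated correlation. Other imprinted genes (10 rose and 2 fell of 15, median 2.08, 1.40 at the bound, adjusted p = 0.00284) included Igf2, at least 66.1-fold higher. Stress response genes (11 rose and 1 fell of 16, median 1.53, 1.365 at the bound, adjusted p = 0.00217) included Egr1, an immediate early gene, 23.3-fold higher. DNA methylation and polycomb genes had 8 higher and 3 lower of 15 (median 1.15 with or without the bound, adjusted p = 0.0175), and primed and early lineage genes 3 higher of 7 (median 0.88, 0.84 at the bound, adjusted p = 0.0213). Interferon and MHC class I genes had 9 lower and 2 higher of 14 (median -1.38, -0.92 at the bound, adjusted p = 0.0107), with B2m falling by 3.55 on the log2 scale and the peptide transporter gene Tap2, above background in 1 of 3 lines, by at least 22.1-fold. Hox clusters (5 of 7 lower, adjusted p = 0.0653), cell cycle (5 higher and 2 lower of 17, adjusted p = 0.457) and housekeeping genes (2 of 8 higher, adjusted p = 0.286) did not pass as lists. Both measured Dlk1-Dio3 genes rose, with Dlk1 at 8.67 ± 1.54 (n = 3). Of the 4 reprogramming factors Pou5f1, Sox2 and Klf4 rose and Myc fell, and of 3 measured sex-linked genes 1 fell: the X-inactivation transcript Xist, above background in 1 of 3 lines, went from 11.89 to 5.33 ± 0.36 (n = 3).

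In limma 5513 of 9263 genes differed, 2743 higher and 2770 lower in the lines, and 3908 of them by at least 2-fold. The even split depends on the processing: it was 3305 higher and 2613 lower with arrays scaled to a common median, 2601 and 3171 with cyclic loess, and 2729 and 1905 with the filter of 3 arrays. Counts adjusted over the list alone differed from those above in the fibroblast or feeder list (12 higher), the germline list (11 higher) and the cell cycle list (4 higher, 1 lower). The single LinNeg_BM array was assumed to vary like the lines, so the p-values leave out variation between bone marrow preparations.

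The second comparison set the lines against ESC, the pluripotent control of the same strain. Core pluripotency genes stood at nearly the same level in both: Pou5f1 differed by -0.07, Nanog by -0.14, Sox2 by -0.08 and Klf4 by -0.19 on the log2 scale, each with an adjusted p of 0.74 or above in limma. No gene passed the test (0 of 9263 in limma, lowest adjusted p = 0.335), and 956 had an unadjusted p under 0.05, 527 of them higher in the lines. The share of tested genes with such a p-value exceeded the 0.05 that no difference would give, also in the other comparisons. Genes taken for a wide gap between ESC and the nearest line, none past the test, included Kcnk1 (2.16), Svop (1.60) and Slc40a1, the iron exporter ferroportin (1.55), with all 3 lines higher. Epha1 and Insm1, below background in ESC, were at least 2.92-fold and at least 1.49-fold higher. With all 3 lines lower were Ephx2 (-1.59), 1700016D06Rik (at least 3.38-fold, above background in 2 of 3 lines) and Aldh3a1 (at least 3.74-fold, above background in 1 of 3 lines). Apcdd1 and Has3, below background in all 3 lines, were at least 2.72-fold and at least 1.51-fold lower. Of these genes Kcnk1, 1700016D06Rik and Has3 lie on chromosome 8. Its genes as a whole stood higher in lines 1.1.2, 7 and 9 than in ESC, by 0.10, 0.28 and 0.40. That is the direction of Kcnk1 but opposite to the lower levels of 1700016D06Rik and Has3.

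Extraembryonic endoderm genes stood higher in the lines than in ESC as a list, with 14 of 14 above 0 and a median of 0.90 (0.75 at the bound; limma's camera, adjusted p = 8.87e-05; adjusted p = 0.811 with an estimated correlation). The median was 1.44 in line 1.1.2, 0.24 in line 7 and 0.89 in line 9, and Dab2 differed by 1.25 and Amn by 1.21. Epithelial junction genes had 13 of 14 above 0 and a median of 0.79 (0.75 at the bound, adjusted p = 1.65e-05, and adjusted p = 0.811 with an estimated correlation), and 6 members passed when adjusted over the list alone: Cdh1, Cldn3, Cldn4, Cldn6, Cdh3 and Grhl2. Their list median above ESC was 0.45, 0.86 and 1.07 in lines 1.1.2, 7 and 9. It was also 0.79 in MEF_iPSC and 0.56 in LinPos_iPSC, so ESC was the array that differed. Beside both lists, fibroblast or feeder genes had 16 of 17 above 0 and a median of 0.63 (0.48 at the bound, adjusted p = 1.74e-04, and adjusted p = 0.811 with an estimated correlation), with Col3a1 and Ccn1 higher and Tgfbi lower when adjusted over the list alone. None of the 5 blood cell lists passed, and their medians lay between -0.03 and 0.06, with a mean of -0.01 beside a median of 0.05 for hematopoietic stem and progenitor genes. Most of their members were below background in both groups, so these medians say little about the genes' levels. Lefty1 and Atf3 were the only other list members past the test when adjusted over the list alone. A simulated log2 difference of 1 was recovered for 12% of genes at this design, so differences of that size between the lines and ESC were mostly not detectable.

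The third comparison set the lines against iPSCs made from fibroblasts. Ctsc, the protease cathepsin C that activates granule proteases of blood cells, stood at 8.77 ± 0.14 (n = 3) in the lines and was not above background in MEF_iPSC, at least 9.15-fold higher (limma, adjusted p = 0.00999). Ctsc also stood at 10.02 in LinNeg_BM, 8.93 in ESC and 8.24 in LinPos_iPSC, so MEF_iPSC was the array that differed. Also higher were Atf4, a transcription factor of the amino acid and stress response (9.48-fold), the apolipoprotein gene Apoa2 (at least 6.42-fold), Zfp365 (5.57-fold) and Tomm22, of the mitochondrial import pore (4.92-fold). Thumpd1 was at least 21.6-fold lower (adjusted p = 0.00338) and the Y-linked Eif2s3y at least 4.57-fold lower (adjusted p = 0.0122).

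Extraembryonic endoderm genes had 14 of 14 above 0 against MEF_iPSC, with a median of 1.13 (0.86 at the bound; limma's camera, adjusted p = 1.73e-05), and fibroblast or feeder genes 16 of 17 with a median of 0.38 (0.21 at the bound, adjusted p = 0.0141). Both of these calls, and those of the next 2 lists, were lost at adjusted p = 0.824 with an estimated correlation. The p53 and cell-cycle inhibitor list had a median of 0.62 (the same at the bound, adjusted p = 1.28e-04). Its members Cdkn1a, Mdm2, Ccng1, Sesn2, Phlda3 and Trp53inp1 passed when adjusted over the list alone, with differences of 1.81 for Trp53inp1 and 1.52 for Ccng1. Relative to ESC the list median was -0.36 in MEF_iPSC and 0.25 in LinPos_iPSC. In lines 1.1.2, 7 and 9 it was 0.34, 0.27 and 0.14, so MEF_iPSC was the array that differed. Stress response genes had a median of 0.33 (0.28 at the bound, adjusted p = 0.00419), with Atf4 past the test over all genes. None of the 5 blood cell lists passed, although 2 lymphoid genes were lower when adjusted over the list alone. The erythroid-megakaryocyte-mast list had a median of 0.02 and a mean of -0.12, and the stem and progenitor list a median of 0.01 and a mean of -0.03. Gaps that did not pass were Emb (-3.97), Crxos (-2.02) and Osm (at least 4.13-fold lower, above background in 2 of 3 lines).

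In limma 7 of 9263 genes differed, 5 higher and 2 lower in the lines, with 1201 at an unadjusted p under 0.05. The count was 0 without line 1.1.2, 2 without line 7 and 1 without line 9, and 91 with normexp background correction (59 higher, 32 lower).

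The fourth comparison set the lines against iPSCs made from lineage-positive marrow. Zscan4c, a transcript known from the early embryo, was at least 12.3-fold higher in the lines (9.17 ± 0.17, n = 3; limma, adjusted p = 0.0114), and Tcstv3, another, at least 2.95-fold higher. Zfp42, the naive pluripotency marker also called Rex1, was 5.49-fold higher (adjusted p = 0.0229), and Lefty1, a Nodal antagonist, 3.64-fold higher (adjusted p = 0.0479). Zfp42 lies on chromosome 8, which as a whole stood higher in lines 7 and 9 than in LinPos_iPSC. ESC, whose chromosome 8 stood nearly level with that of LinPos_iPSC, nevertheless had Zfp42 at 12.22. Other genes higher in the lines were Trim59 (at least 8.62-fold), Apoa2 (at least 6.55-fold), Csrp1 (at least 5.71-fold), 2210409E12Rik (9.20-fold), Crmp1 (at least 5.49-fold), Ttc27 (5.73-fold), Casp9 (at least 4.83-fold), Abhd16a (at least 3.86-fold) and Pramel37 (at least 3.35-fold). Other probes did not bear out all of these: those of Casp9 differed by -0.103 and -1.147, so no change is claimed for that gene, and those of Crmp1 and Pramel37 showed 13.3% and 29.0% of the difference. Zscan4c stood at 8.53 in ESC and 8.57 in MEF_iPSC, Tcstv3 at 7.07 and 7.38, and Zfp42 at 12.22 and 11.60. For these, and for Trim59, Csrp1, Ttc27 and Abhd16a, LinPos_iPSC was the array that differed. Lefty1 was instead highest in the lines (11.19 in ESC, 10.89 in MEF_iPSC), and Apoa2 and 2210409E12Rik were also low in MEF_iPSC. Lower in the lines were Aspg (at least 1.93-fold) and, each above background in line 1.1.2 only among the 3 lines, Vax2 (at least 6.10-fold) and B3galt6 (at least 4.91-fold).

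**Figure D3:**
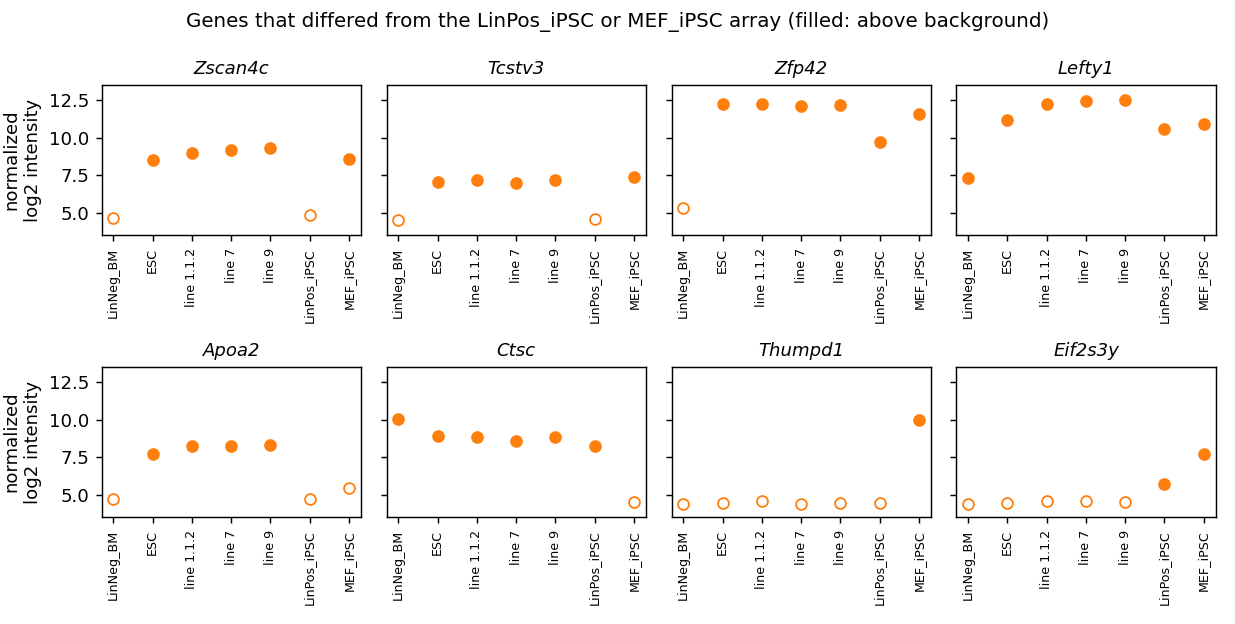
Normalized log2 intensity (vertical axis) of 8 genes past the test against LinPos_iPSC or MEF_iPSC on each of the 7 arrays (horizontal axis), with 1 point per array, filled where above background and open where not. Zscan4c stood at 9.17 on average in the 3 lines and below background in LinPos_iPSC, and Thumpd1 was above background in MEF_iPSC only.

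Other pluripotency genes did not pass: Pou5f1 differed by -0.17 and Nanog by -0.22 on the log2 scale. Of the 26 naive pluripotency genes 1 passed over all genes, and 3 were higher and 4 lower when adjusted over the list alone. The germline and early-embryo list had 2 genes higher of 12 (median 0.23, 0.12 at the bound; limma's camera, adjusted p = 0.0979). Extraembryonic endoderm genes had 12 of 14 above 0 and a median of 0.62 (0.52 at the bound, adjusted p = 0.0229), and fibroblast or feeder genes 15 of 17 and a median of 0.64 (0.58 at the bound, adjusted p = 0.0141). Both stood at adjusted p = 0.76 with an estimated correlation. None of the 5 blood cell lists passed. The stem and progenitor list had a median of 0.02 and a mean of -0.13, with 1 gene lower when adjusted over the list alone, and Gata2, above background in 1 of 3 lines, was at least 2.85-fold lower without passing (adjusted p = 0.097 in limma over all genes).

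In limma 29 of 9263 genes differed, 26 higher and 3 lower in the lines, with 1494 at an unadjusted p under 0.05. The count was 0 without line 1.1.2, 0 without line 7 and 0 without line 9. The split was also unstable: 123 higher and 93 lower with normexp background correction, 144 and 125 without background correction, and 127 and 75 with trend and robust.

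Bone marrow genes were then followed into the lines to ask whether they stayed higher there than in fibroblast-derived iPSCs. Among 894 genes at least 4 times brighter in LinNeg_BM than in ESC, the median LinNeg_iPSC minus MEF_iPSC difference was 0.01, at percentile 10.4 of 10000 matched random lists. The lines disagreed: the median was -0.02 in line 1.1.2 (percentile 0.74), 0.01 in line 7 (percentile 80.3) and 0.02 in line 9 (percentile 98.9), and it was -0.01 in LinPos_iPSC (percentile 17.1). Of these genes 392, 406 and 395 were above background in lines 1.1.2, 7 and 9, against 379 in MEF_iPSC and 370 in LinPos_iPSC. That is 41.39% to 45.41% of the genes, so most values lay at background on each of these arrays. The medians therefore say little about whether bone marrow genes stayed higher in the lines. With 1 MEF_iPSC array no p-value was given, and the percentile ran from 3.63 to 100 over the alternatives.

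Across genes, the 3 lines correlated with ESC at a mean Pearson r of 0.983 ± 0.0037 (SD, n = 3), with MEF_iPSC at 0.980 ± 0.0014 (n = 3), with LinPos_iPSC at 0.976 ± 0.0012 (n = 3) and with LinNeg_BM at 0.698 ± 4e-04 (n = 3). Line 1.1.2 was the closest to ESC, at 0.987, with 2.04% of genes at least 2-fold apart, against 3.93% for line 7. The higher mean with ESC than with MEF_iPSC came mostly from line 1.1.2, at 0.9871 and 0.9781. Line 7 stood at 0.9811 and 0.9804, and line 9 at 0.9804 and 0.9806. Line 1.1.2 correlated as closely with ESC as with line 7 (0.9871) and line 9 (0.987), and lines 7 and 9 correlated at 0.9895. It also shares the low chromosome 14 block with ESC described below. The lowest correlation among pluripotent arrays was 0.970, between LinPos_iPSC and MEF_iPSC. Between the lines and LinNeg_BM 43.2% to 43.8% of genes were at least 2-fold apart. Genes are not independent replicates, and no test was made of these correlations.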

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

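Both counts below were chosen only after it was seen that some probes had no gene name. Probes without a named gene took no part in the main comparisons and entered only the alternative over all probes. Of them, 765 of 1719 (44.5%) were above background on at least 1 array, against 116.8 if every one had been at background. Over all 25697 probes, named or not, 13427 were above background on at least 1 array. Against LinNeg_BM, 458 of the 765 unnamed probes differed in limma, 248 higher and 210 lower in the LinNeg_iPSC lines, beside 5513 of 9263 named genes. Of all 765, 80 were above background on all 6 pluripotent arrays and not in LinNeg_BM, and 64 in LinNeg_BM only.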

How the results depend on the processing

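The fits without chromosomes X and Y or without chromosomes 8 and 14 were chosen only after the data were seen. Against ESC the count was 0 under every alternative run. Against LinNeg_BM it stayed within 1.5 times of 5513, from 3908 with the 2-fold minimum to 7932 over all probes, and without each line it ran from 4890 to 5335. The MEF_iPSC count of 7 became 91 with normexp, 97 without background correction, 69 with trend and robust, 3 in the authors' values, 3 with the other pluripotent arrays pooled, and 0 to 2 without each line (0 without line 1.1.2). The LinPos_iPSC count of 29 became 216 with normexp (123 higher, 93 lower), 269 without background correction (144 higher, 125 lower), 202 with trend and robust (127 higher, 75 lower), 68 with a common median, 11 in the authors' values, 19 with no filter, 51 with 3 arrays above background, and 0 without each line in turn. Leaving out a line leaves fewer arrays to estimate the spread; the cause of the other changes was not tested. Without X and Y genes MEF_iPSC gave 6 and LinPos_iPSC 28, and without chromosomes 8 and 14 they gave 7 and 28.

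Retention moved from 0.01 to 0.13 with a common median, 0.055 with loess and 0.038 in the authors' values, and its percentile was 82.8 without line 1.1.2, 12.9 without line 7 and 10.1 without line 9. Correlation with ESC (0.983) was 0.988 without background correction, 0.976 in the authors' values, 0.989 with no filter and 0.979 with 3 arrays above background. Correlation with LinNeg_BM (0.698) was 0.732 with normexp, 0.746 without background correction, 0.693 with a common median, 0.679 with loess, 0.637 in the authors' values, 0.836 with no filter and 0.731 with 3 arrays above background. Scaling to a common median put the median of all genes against LinNeg_BM at 0.15 instead of 0.02. The list calls kept their side under the other backgrounds and normalizations and were all lost with an estimated correlation. Some lists not called in the main fit gained a call. Against ESC these were 2 without background correction, 1 with normexp and 1 with a common median. Against MEF_iPSC it was 1 without background correction, and against LinPos_iPSC 2 with normexp and 1 without background correction. Over all alternatives, results for named genes past the test were kept 1305 times and lost 8 times against LinNeg_BM, 74 and 28 times against MEF_iPSC, and 167 and 71 times against LinPos_iPSC, and none reversed. Named genes not past the main test gained a call 10 times against LinNeg_BM, 42 times against MEF_iPSC, 57 times against LinPos_iPSC and 0 times against ESC. A slide block was not run, because the columns give no slide. No paired analysis was possible because all groups but LinNeg_iPSC hold 1 array. Near background a small change of intensity moves the log2 value by much, which limits the dim genes.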

Other observations

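Of the tests below, the random lists for chromosome 8, the neighbour count, the brightness test of Eif2s3y and Xist, and the copy-loss and normalization tests of the chromosome 14 block were chosen only after the result was seen, the overall chromosome 8 difference was known before its other tests, and the rules for judging the chromosome share, the X-linked difference and the admixture ceiling were revised after their values were seen.

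The 12 genes with the largest SD between the 3 LinNeg_iPSC lines, chosen after their values were seen, are given in order of that SD, as levels in lines 1.1.2, 7 and 9. Dcn, the proteoglycan decorin, stood at 6.27, 10.33 and 6.98, the X-linked Tex13b at 9.59, 6.77 and 6.92, the imprinted Dlk1 at 7.75, 10.45 and 7.83, and Ptn at 6.61, 9.51 and 7.36. Lum, the proteoglycan lumican, stood at 4.60, 6.92 and 4.72, Srgn at 7.08, 4.74 and 6.38, Lyz1, a lysozyme, at 4.81, 6.80 and 4.68, and Ly6c1 at 5.83, 7.86 and 5.81. Spink1 stood at 9.95, 7.88 and 9.84, Emb at 7.79, 6.68 and 8.96, Foxq1 at 8.63, 6.43 and 7.51, and Gata6, a transcription factor of primitive endoderm, at 8.35, 6.22 and 7.69. Of these, Lum and Lyz1 were below background in lines 1.1.2 and 9, and Srgn in line 7. Of the 17 fibroblast or feeder genes 10 were highest and 4 lowest in line 7, and of the 14 extraembryonic endoderm genes 1 was highest and 13 were lowest. With 1 array per line these differences have no replicate check.

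Xist stood at 11.89 in LinNeg_BM and between 4.85 and 5.72 on the 6 pluripotent arrays. The Y-linked Eif2s3y was above background in MEF_iPSC (7.73) and LinPos_iPSC (5.72) and on no other array, while Uty, the other Y-linked gene tested, was above background in LinNeg_BM (5.69) and line 9 (5.82) and on no other array. A global brightness difference is argued against as the cause of the Eif2s3y level of MEF_iPSC and the Xist level of LinNeg_BM, since at most 0.106% of 5651 autosomal genes differed as much in deposited intensity in any of the 10 array pairs, a test that replaced one on the median difference (at most 0.72), whose bound of 1 with the spread of 0.793 added had left it undecided. X-linked genes stood 0.094 higher than autosomal genes in LinNeg_iPSC minus MEF_iPSC, with 0 of 10000 matched random lists as high. By line the difference was 0.071 in line 1.1.2, 0.092 in line 7 and 0.09 in line 9. ESC, where Eif2s3y was also below background, gave 0.051 against MEF_iPSC, inside its random range (602 lists as high), and LinPos_iPSC gave -0.008. The mean difference of 0.094, and that of each line, lay under 0.1, the bound preset as counting against 2 active X chromosomes in the lines. By that preset rule these values argue against 2 active X chromosomes, with 1 MEF_iPSC array as the reference. Only the rule revised after the values were seen, which adds the spread, left 2 active X chromosomes undecided. A brightness difference shared by all genes cancels when autosomal genes are subtracted. Each line also lay above the central range of its matched random lists, whose upper ends were 0.051, 0.04 and 0.041 in lines 1.1.2, 7 and 9. Both argue against such a brightness difference as the source of the X-linked shift. Shifts of -0.10 outside all random lists were also seen for autosomes, such as chromosome 3 in MEF_iPSC minus ESC.

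Genes of chromosome 8 (374 measured on all pluripotent arrays) stood higher than in ESC, relative to other autosomes, by 0.44 in MEF_iPSC, 0.40 in line 9, 0.28 in line 7 and 0.10 in line 1.1.2, against 0.02 in LinPos_iPSC. The normalization is argued against, since the MEF_iPSC difference was at least 0.368 under 5 other backgrounds and normalizations, and probe brightness too, since 0 of 10000 matched random lists were as high. An extra copy of the chromosome in some or all cells may explain it: 3 parts of the chromosome, split by position, shifted by 0.449, 0.402 and 0.526 in MEF_iPSC, each under the size of 1 extra copy in all cells. Against LinNeg_BM the chromosome stood at 0.47 in MEF_iPSC, 0.36 in line 9 and 0.21 in line 7, above the central range of random lists, and at 0.08 in line 1.1.2, inside its range of -0.08 to 0.17, as were -0.01 in ESC and 0.06 in LinPos_iPSC. No DNA was measured, and a change of regulation along the whole chromosome stays open.

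A block of 86 neighbouring genes on chromosome 14, from Mapk8 to Pinx1 in the order of GRCm38.p6, stood lower in ESC (-0.90) and line 1.1.2 (-0.66) than the mean of the other 4 pluripotent arrays, with 95.3% and 93.0% of its genes below that mean. The block found from ESC minus line 9 and the block found from line 1.1.2 minus line 7, which share no array, were the same 86 genes, and in it line 1.1.2 minus line 7 was -0.726. The normalization is argued against, since 5 other settings gave -0.549 or lower. RNA or cells of this ESC sample in line 1.1.2 are argued against too, since elsewhere in the genome line 1.1.2 carried 16.47% of the ESC difference from line 9, against 57.8% needed for its share of the block and 15.5% in MEF_iPSC. A loss of 1 of 2 copies of the segment, which would give -1 in all cells, may explain both arrays, and whether the cultures share an ancestor, lost it separately or carry a wrong sample label (the labels' tissue field reads bone marrow for ESC too) was not tested.

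The 34 genes past the test against LinPos_iPSC or MEF_iPSC form the last pattern. At most 17.65% of them (6 genes, exact 95% interval 6.76% to 34.5%) lay on 1 chromosome. This share cannot decide on a gain or loss of a whole chromosome in the lone line. It pooled both comparisons, so the 7 genes past the test against MEF_iPSC could not make up most of the 34. The smallest difference past the test was 1.617 against LinPos_iPSC and 2.299 against MEF_iPSC. Loss of 1 of 2 copies would give -1 in the lone line, smaller in size than any difference that passed. The widest chromosome shift, 0.245 on chromosome 8, lay near the preset bound of 0.25. A sequence variant under the probe cannot be told apart from a real change: the 10 other probes, of 7 of these genes, showed a median of 58.51% of the change, from -40.01% to 127.7%. Blocks of neighbouring genes, as segments inherited from different parents would give, may contribute, since 10 pairs lay within 5 Mb of each other and 108 of 10000 random sets had as many. The pairs include related genes that lie side by side, such as Tcstv3 and AF067061, so shared regulation or probes shared within a gene family stay open, as does the cell of origin, which was not tested.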
